A study of Mus musculus with 12 samples.

How the data were processed

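Polyadenylated RNA of 12 mouse samples in 4 groups of 3 was sequenced. Per the labels, the samples were T-cell acute lymphoblastic leukaemia (T-ALL) cells from the thymus and from the spleen of overtly sick LN3 mice, a transgenic leukaemia model on the C57BL/6 background, and, from tumour-free C57BL/6J mice, thymocytes and spleen CD8 T cells. Organs were dissociated mechanically, and only the control spleen cells were enriched, by negative selection of CD8 T cells to a stated purity of 85 to 95%. RNA was selected for poly(A) tails, made into strand-keeping libraries and sequenced as read pairs on an Illumina instrument, per the labels. The labels do not say that all samples of a group came from separate animals, so p-values measure only the spread between these samples, which may in part be technical. Xist was at 1670 CPM of library totals or more in 1 or 2 libraries of each group and at 3.43 or less in the others, so that each group held at least 2 animals.

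The deposited count table holds estimated counts per gene, made by the authors before deposit. The submitters' processing notes name kallisto 0.46.1, a pseudoaligner that assigns read pairs to transcripts, FastQC, DESeq2 and genome build GRCm38. The versions of FastQC and DESeq2, the annotation release and whether kallisto used the strand are not given in the sources used here. Of 652212 deposited estimated counts, 100% were already whole numbers, and rounding was applied anyway. A second table deposited by the authors holds variance-stabilized values on a log2 scale, which were used only in an alternative test. Kallisto shares read pairs between near-identical transcripts by estimation, so values of close gene copies (receptor V segments, haemoglobin, histone, killer receptor, Ifit and Ly6 genes, and the pair Il22 and Iltifb) are less certain than those of other genes. All columns of both tables were assigned to a sample by name.

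Total counts per library ran from 12694571 to 42483898. A count of 3, taken as the floor per library for genes without a count, corresponds to 0.0657 to 0.262 CPM (counts scaled to a common library total with TMM factors). Confidence intervals of shares are exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since read pairs without molecular identifiers are not independent molecules.

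Of 54351 genes, 16997 had no count in any library, and 20897 passed edgeR's filterByExpr and were tested. Fits used edgeR 4.0.16 in R 4.3.3 with TMM scaling, a design of 4 group means over all 12 libraries (8 residual degrees of freedom), robust dispersions and the quasi-likelihood test. The common biological coefficient of variation was 0.4411. A gene was called when its Benjamini-Hochberg adjusted p over all genes tested was below 0.05. The contrasts were LN3 against wild-type (WT) in the thymus, LN3 against WT CD8 T cells in the spleen, LN3 spleen against LN3 thymus, WT CD8 T cells against WT thymocytes, and the difference of the first pair of contrasts (the interaction of tissue and genotype). Adjusted p-values of single genes are from this test and those of lists from limma's camera, unless another tool is named. CPM are given with the SD over the 3 libraries of a group. A fold against a group without counts is a lower bound, computed from the floor of 3 counts per library, and a fold against a group of 1 to 3 counts is a ratio of summed counts per summed scaled total, with its 95% counting interval, which can differ from the ratio of mean CPM.

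Genes were also described as lists: 20 programme lists, 7 lists of markers of other cells and 3 lists of RNA quality or sex. The programme lists were progenitor transcription factors, the HoxA cluster, the Notch pathway, double-positive thymocyte genes, mature naive T-cell genes, G2/M phase, DNA replication, ribosome biogenesis, glycolysis, integrins, receptor tyrosine kinases, cytokine receptors, chemokine receptors, T-cell receptor signalling, interferon response, MHC class I presentation, cytotoxic effectors, the BCL2 family, T-ALL tumour suppressors and immune checkpoints. The lists of other cells were myeloid, dendritic, B cell, erythroid, NK cell, stroma and platelet markers, and the last 3 were dissociation stress, mitochondrially encoded and sex-linked genes. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 30 lists of a comparison, and again with the correlation estimated from the data. The calls that held with an estimated correlation were the Notch and double-positive lists in the thymus, those and the tumour suppressors in the spleen, and the double-positive list in the WT contrast and in the interaction.

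Groups, contrasts, tests, lists and the rule for named genes were chosen before the data were examined. The rule took 8 anchor genes (Lmo2, Hoxd13, Nup98, Notch1, Myc, Igf1r, Cd4 and Cd8a) whatever their values. Of each programme list described, it took the 2 called members with the largest change in the main direction and 1 in the other, at 5 CPM or more in the higher group. Per contrast it took up to 5 called genes with the largest rise and up to 5 with the largest fall whose libraries did not overlap between the groups, leaving out receptor and immunoglobulin segments, pseudogenes and unnamed or provisional genes. For the interaction, the condition on overlap was not applied. Of each list of other cells and of quality it took the 2 most abundant members. A few genes that the rule took are not reported here. Shares of counts per library were compared by exact two-sided permutation tests of group means, which cannot go below 0.1 with 3 against 3 libraries.

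The fit was tested on simulated counts with 200 genes changed, drawn from genes above 2 CPM in the reference group. For the thymus contrast (19122 genes), 2%, 64%, 88% and 94% of genes changed 2-fold, 4-fold, 8-fold and 16-fold were called. The same shares were 0%, 56%, 96% and 96% for the spleen contrast (19485 genes) and 12%, 66%, 84% and 94% for LN3 spleen against thymus (18861 genes). False calls were 4 of 128, 8 of 132 and 3 of 131, with 0 of the wrong sign. The simulation drew genes independently, without effects shared within a library, and changed equal numbers up and down. It therefore does not cover false calls that come from GC shifts between libraries or from the choice of scaling. Changes in genes at lower levels were not covered either. LN3 against WT called 11.26% of genes in the thymus and 30.88% in the spleen, a larger share than was changed here.

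Alternatives chosen at the same stage were RLE factors, library totals and upper-quartile factors as scaling, DESeq2 1.42.0, limma on the variance-stabilized values, no filter, a filter of 1 CPM in 3 libraries, fits of the 2 groups alone, the replicate number as a block, each library left out, no receptor, immunoglobulin, haemoglobin and mitochondrial genes, and a test against a fold of 1.5. Chosen after seeing the data were corrections for GC content and for transcript length, the ribosomal RNA feature CT010467.1 as a covariate, and a fit without WT thymocyte 3, LN3 thymus 2 and LN3 spleen 1, whose counts rose most with GC content. Positions, lengths and GC content were taken from GENCODE M21 on GRCm38 by gene symbol, where 53774 of 54351 symbols matched and 53668 had a single position. No pair of libraries of a group was a duplicate, since the chi-square per degree of freedom of their counts was 22.14 or more. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.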

Results

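Transcriptomes of T-ALL cells were compared with those of normal T-lineage cells in 2 organs. The 4 groups of 3 libraries were T-ALL cells from the thymus and from the spleen of LN3 mice, thymocytes of tumour-free mice (WT thymocytes), and spleen T cells of tumour-free mice enriched for CD8 (WT CD8 cells). Libraries 1 to 3 had total counts of 20338814, 16229176 and 37273890 in LN3 thymus and of 12820498, 12694571 and 13592535 in WT thymocytes. The totals were 14341613, 35852952 and 21457736 in LN3 spleen and 15629090, 26881541 and 42483898 in WT CD8 cells. The first principal component of log2 CPM held 39.96% of the variance and the second 19.58%. The 6 LN3 libraries lay at −64.33 or lower on the first component and the 3 WT CD8 libraries at 125.3 or higher, with WT thymocyte libraries between them. WT thymocyte 3 stood apart from the other WT thymocyte libraries on the third component (15.06% of the variance), at −138.3 against 0.1556 and 44.33.

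**Figure D1:**
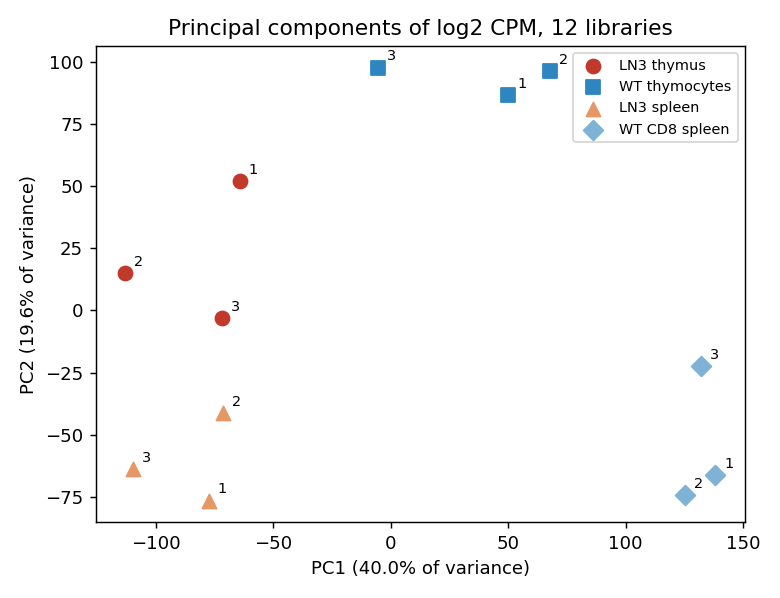
First (x axis, 39.96% of variance) and second (y axis, 19.58%) principal components of log2 CPM, one point per library, coloured by group. The 6 LN3 libraries lie on the left, between −113 and −64.33, and WT thymocyte 3 lies at −5.449, away from WT thymocytes 1 and 2 at 49.98 and 67.9.

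The first comparison asked how thymic T-ALL cells differed from thymocytes of tumour-free mice. The LN3 cells had higher levels of the receptor Notch1 and of Notch target genes and of the transcription factor Myc, and lower levels of genes that mark double-positive thymocytes. The Notch pathway was higher in 8 of 11 genes and the double-positive list lower in 10 of 15, and both list calls held with an estimated correlation. Ribosome biogenesis genes were higher in 9 of 18 cases, a list whose call was lost there (adjusted p = 0.285 with an estimated correlation). Notch1 (chromosome 2, 26457903 to 26516663 on GRCm38) was 5.15-fold higher, at 2339 ± 428 against 453.8 ± 162 CPM (log2 difference 2.37, SE 0.39, adjusted p = 0.00231). Myc, a driver of cell growth, was 4.61-fold higher, at 305.3 ± 85.7 against 66.17 ± 23.7 CPM (log2 difference 2.21, SE 0.30, adjusted p = 0.000682), and Igf1r, the receptor of insulin-like growth factor 1, 3.52-fold higher (log2 difference 1.82, adjusted p = 0.0101). The co-receptor gene Cd4 fell by 4.71 on the log2 scale (SE 0.83, adjusted p = 0.00349), from 1121 ± 390 to 42.79 ± 41.7 CPM, and Cd8a fell by 2.64 (SE 0.42, adjusted p = 0.00181), from 1845 to 296.3 CPM. Without the 3 libraries with the strongest rise of counts with GC content, the calls of Cd4 (adjusted p = 0.0572), Rag1 (0.12), Kit, Hk2, Gzma, Ctla4, Vsir, Bcl11b, Prim1, Il22 and Mgam ended. Lmo2, a transcription factor gene active in some T-ALL, did not differ by more than the spread between libraries (log2 difference 1.26, adjusted p = 0.413), nor did the nucleoporin gene Nup98 (0.20, adjusted p = 0.587). Hoxd13 had no count in any of the 12 libraries, which at these depths allows up to 0.0657 to 0.262 CPM per library.

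Of 11 measured Notch pathway genes, 8 were higher in LN3 thymus, and 8 when adjusted over the list alone (median log2 difference 2.21, camera adjusted p = 7.98e-11, adjusted p = 0.0106 with an estimated correlation). The Notch target Heyl (chromosome 4, 123233556 to 123249875) rose from 0.655 ± 0.273 to 58.99 ± 4.88 CPM (log2 difference 6.51, SE 0.54, adjusted p = 2.05e-05), and Hes1 (chromosome 16, 30064384 to 30067796) from 2.927 to 57.29 CPM (4.30, SE 0.61, adjusted p = 0.000889). Of 15 double-positive thymocyte genes, 10 were lower, and 12 were lower and 1 higher when adjusted over the list alone (median −1.48, camera adjusted p = 1.37e-09, adjusted p = 0.01 with an estimated correlation). The recombinase gene Rag1 (chromosome 2, 101638282 to 101649501) fell by 3.25 (SE 0.73, adjusted p = 0.0127), from 4871 ± 469 to 512.9 ± 369 CPM, a call that ended without LN3 thymus 2 (adjusted p = 0.0547). Of the HoxA cluster, 3 genes were measured and 2 were lower, 3 adjusted over the list alone (camera adjusted p = 0.000169, adjusted p = 0.197 with an estimated correlation). Hoxa7 fell by 6.52 (adjusted p = 0.000438). Progenitor transcription factors had 2 lower genes of 14, 3 adjusted over the list alone (camera adjusted p = 0.00236, adjusted p = 0.638 with an estimated correlation). Among them was Kit, the receptor of stem cell factor (−2.06, adjusted p = 0.0125).

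Genes of ribosome biogenesis were higher in 9 of 18 cases, and in 14 when adjusted over the list alone (median log2 difference 1.06, camera adjusted p = 3.69e-09, adjusted p = 0.285 with an estimated correlation). Npm1, which encodes a nucleolar chaperone, rose from 242.8 to 976.2 CPM (2.01, adjusted p = 0.0039), and Gnl3, a nucleolar GTPase gene, was 3.6-fold higher (adjusted p = 0.00377). Of 16 glycolysis genes, 2 were higher (7 with library totals as scaling), and 9 when adjusted over the list alone (camera adjusted p = 0.00468, adjusted p = 0.697 with an estimated correlation). Hk2, hexokinase 2, was 5.23-fold higher (adjusted p = 0.00833). The glycolysis call ended without LN3 thymus 2 or WT thymocyte 2 (adjusted p up to 0.0828). Of 24 DNA replication genes, 1 was called, also when adjusted over the list alone: Prim1, a primase subunit (1.19, adjusted p = 0.0119, and 0.0682 without WT thymocyte 1). That list's median was 0.63 (camera adjusted p = 0.0119, adjusted p = 0.734 with an estimated correlation), and its camera call ended without LN3 thymus 1, LN3 thymus 2 or WT thymocyte 2 (up to 0.121). Of 20 genes of the G2/M phase, edgeR, DESeq2 and limma each called 0, with 0 at an unadjusted p under 0.05 and a median difference of 0.349 (camera adjusted p = 0.108). Mitochondrially encoded genes were higher in 9 of 13 cases, 11 adjusted over the list alone (camera adjusted p = 6.28e-08, adjusted p = 0.259 with an estimated correlation), and took 2.86 ± 0.634% of counts against 1.4 ± 0.427% (exact two-sided permutation p = 0.1, the smallest possible; 0.222 adjusted over 20 such tests).

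Receptor genes moved in both directions. Of 22 receptor tyrosine kinase genes, 6 were higher and 2 lower, and 6 and 5 when adjusted over the list alone. The median was −0.502, the mean 0.457, and the list as a whole did not pass (camera adjusted p = 0.47). Pdgfrb, the beta receptor of platelet-derived growth factor (chromosome 18, 61045150 to 61085061), rose 98.1-fold, from 6.45 ± 1.82 to 631.6 ± 147 CPM (log2 difference 6.62, SE 0.44, adjusted p = 5e-06). Irs1, an adaptor of insulin receptors, was higher by 5.25 (adjusted p = 0.00205), and the neurotrophin receptor Ntrk3 fell by 2.10 (adjusted p = 0.000429). Of 22 cytokine receptor genes, 9 were lower and 3 higher, and 10 and 4 adjusted over the list alone (camera adjusted p = 0.000917, adjusted p = 0.259 with an estimated correlation). Il4ra fell by 4.27 (adjusted p = 0.000845) and Tgfbr3 by 3.02 (adjusted p = 2.47e-05). In contrast, Il9r was 10.2-fold higher, at 86.55 CPM (adjusted p = 0.000167). Of 18 chemokine receptor genes, 3 were lower, 4 adjusted over the list alone (camera adjusted p = 0.00138, adjusted p = 0.259 with an estimated correlation). Among them, Cxcr6 fell by 2.76 (adjusted p = 9.99e-05) and the thymus-homing receptor Ccr9 by 3.24 (adjusted p = 0.0126, and 0.053 without LN3 thymus 1). Integrins had 4 lower genes and 1 higher of 24, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0216, adjusted p = 0.543 with an estimated correlation). Itgae fell by 2.33 (adjusted p = 0.00456), and Itga9 was 18.3-fold higher (adjusted p = 0.00365). The integrin call ended without LN3 thymus 1, LN3 thymus 2 or WT thymocyte 3 (up to 0.0648).

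Interferon-response genes were lower in 6 of 20 cases, 8 adjusted over the list alone (median −0.994, camera adjusted p = 0.000198, adjusted p = 0.543 with an estimated correlation). Among them was Ifit3 (−2.14, adjusted p = 0.0121). Of 19 genes listed as tumour suppressors in T-ALL, 5 were higher and 2 lower, and 8 and 2 adjusted over the list alone (camera adjusted p = 0.0216, adjusted p = 0.197 with an estimated correlation, and 0.0515 without WT thymocyte 2). The cell-cycle inhibitor Cdkn2a was at 6.474 against 0.07372 CPM, a ratio of 82.4 between summed counts per scaled total, with a counting interval of 28 to 401 (adjusted p = 0.00064), the transcription factor Lef1 rose 2.88-fold (adjusted p = 0.00713), and Bcl11b, which sets T-cell identity, fell by 1.14 (adjusted p = 0.0127), a call that ended without LN3 thymus 2, LN3 thymus 3 or WT thymocyte 1 (up to 0.0615). In the BCL2 family, 4 genes were lower and 2 higher of 16, the same counts adjusted over the list alone (camera adjusted p = 0.232), and the survival gene Bcl2l1 fell by 2.94 (adjusted p = 0.000536). Of 15 mature naive T-cell genes, 4 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.697 with an estimated correlation). Il7r, the interleukin-7 receptor, fell by 2.88 (adjusted p = 0.00543). Of 17 cytotoxic genes, 3 were lower and 1, Gzma (6.34-fold, adjusted p = 0.0054), was higher, and 4 and 1 adjusted over the list alone (camera adjusted p = 0.0232, adjusted p = 0.697 with an estimated correlation). Of 21 genes of T-cell receptor signalling, 3 were lower, also adjusted over the list alone (camera adjusted p = 0.0365, adjusted p = 0.734 with an estimated correlation). The camera calls of the naive and signalling lists ended without LN3 thymus 1 or WT thymocyte 3 (up to 0.296 and 0.466), and that of the cytotoxic list also without LN3 thymus 3 (up to 0.203). Immune checkpoints (1 higher and 2 lower of 14, also over the list alone; camera adjusted p = 0.136) did not pass as a list, although Ctla4 was 8.56-fold higher (adjusted p = 0.00978). For MHC class I presentation edgeR called 0 of 16 genes, against 6 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma. With library totals as scaling edgeR called 5 of them lower, and with upper-quartile factors 1. Its median was 0.219, its mean −0.0755 and its camera direction downward (adjusted p = 0.923).

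Among the genes with the largest rises, Vgll1, a transcriptional cofactor gene (chromosome X, 57088106 to 57106540), was at 89.42 ± 83.6 CPM in LN3 thymus and had no count in WT thymocytes, which made it at least 416-fold higher by group means (adjusted p = 0.0111, and 0.0773 without the 3 libraries with the strongest GC rise). Its log2 difference was 4.26 for LN3 thymus 1 against WT thymocytes 1 and 2. For LN3 thymus 2 and 3 against WT thymocyte 3 it was 10.5. The interleukin-22 genes Iltifb and Il22, near-identical copies, were at least 54.2-fold and at least 38.3-fold higher. Sall3, a zinc-finger transcription factor gene, was at 94.04 ± 21.4 against 0.1085 CPM (adjusted p = 3.77e-05) and Rgma, a guidance molecule gene, at 82.79 against 0.1167 CPM (adjusted p = 3.44e-06). Of the largest falls, Ly6k and Fzd10 had no count in LN3 thymus and were at least 49.7-fold and at least 34.5-fold lower. Mgam and Csgalnact1 were lower by ratios of 428 (76.1 to 17000) and 186 (50.8 to 1540), and Gpc2, a glypican gene, fell by 7.89 (adjusted p = 0.000438).

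edgeR called 1266 genes higher and 1088 lower in this comparison (53.78% higher), 1185 and 999 of them by 2-fold or more, with 5172 genes at an unadjusted p under 0.05. With library totals or upper-quartile factors as scaling, which moved the median of all genes by −0.192 and −0.163, the share of calls that were higher was 38.24% and 41.2%. With library totals, lower genes of T-cell receptor signalling numbered 7 (5 with upper-quartile factors), and higher genes numbered 1 among cytokine receptors, 0 among naive T-cell genes and 1 in the BCL2 family (1 with upper-quartile factors). The count of higher genes was 562 without WT thymocyte 1, 762 without WT thymocyte 2 and 781 without LN3 thymus 2, and that of lower genes 641 without WT thymocyte 1.

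Of the lists of other cells, that of dendritic markers passed in the thymus, with 1 of 15 lower, also adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.697 with an estimated correlation, and up to 0.115 without LN3 thymus 1 or WT thymocyte 3). The dendritic genes Cd74 and H2-Aa were at −0.72 and −0.69 (adjusted p = 0.638 and 0.673), the myeloid genes Lyz2 and Mpeg1 at 0.42 and 0.55 (0.851 and 0.744), and the B-cell genes Ighm and Ighd at −0.25 and 0.55 (0.843 and 0.706). The erythroid genes Hbb-bs and Hba-a1 were at −5.18 and −4.88 (0.0907 and 0.115), with haemoglobin at 0.447% of counts in WT thymocyte 1 (95% interval 0.443 to 0.45) and 0.00132% in WT thymocyte 2 (0.00113 to 0.00154). Camera gave adjusted p = 0.409 for myeloid, 0.136 for B-cell, 0.325 for erythroid, 0.087 for NK-cell, 0.654 for stroma and 0.654 for platelet markers, and 0.381 for dissociation stress and 0.923 for sex-linked genes. The stress gene Jund fell by 2.79 (adjusted p = 0.00768) and Txk, a kinase of T and NK cells, by 1.57 (adjusted p = 0.00152).

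**Figure D2:**
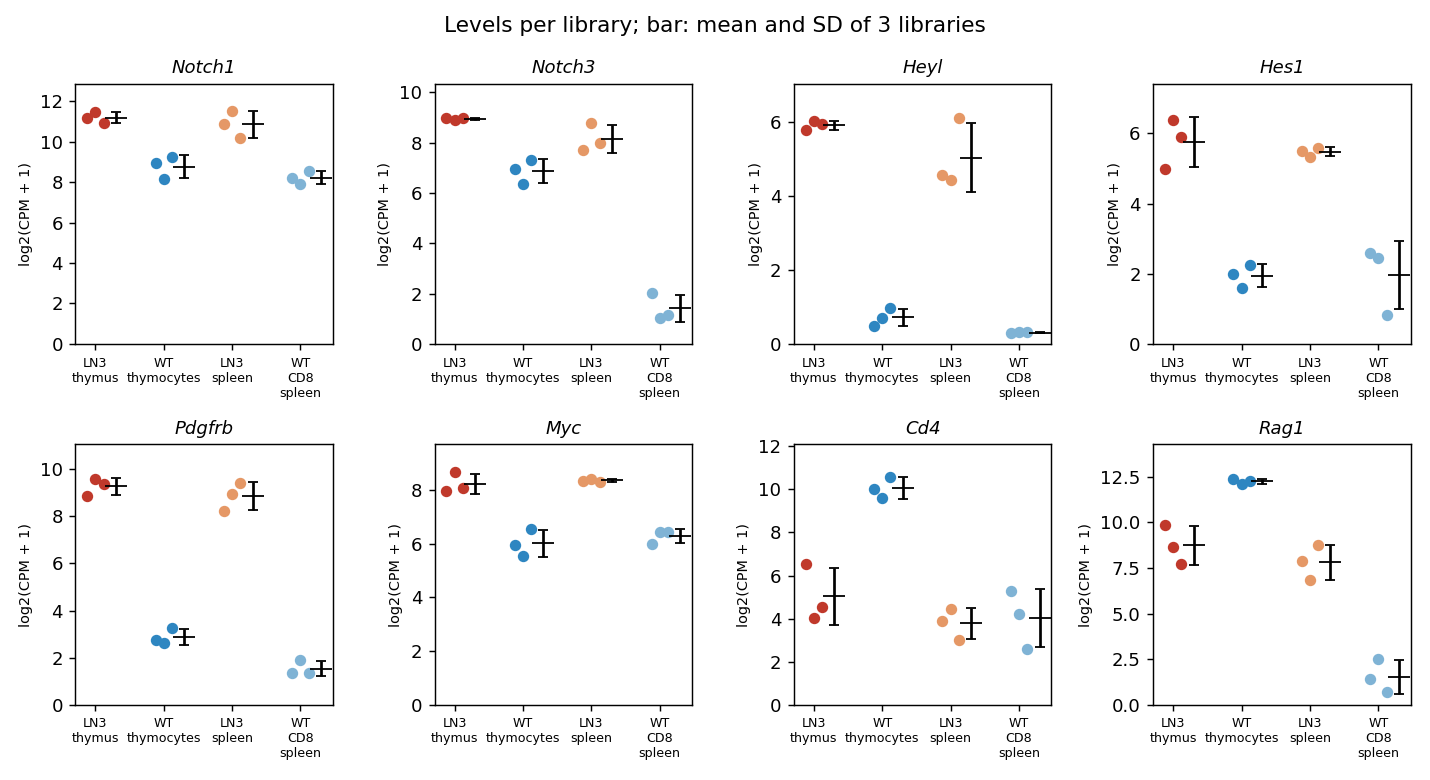
Level of 8 genes per library (y axis, log2 of CPM + 1) in the 4 groups (x axis), with points for libraries and the mean and SD of the 3 libraries of each group. Notch1, Heyl and Pdgfrb are higher in LN3 than in the WT group of the same organ, while Rag1 is at 4871 CPM in WT thymocytes, 512.9 in LN3 thymus, 258.2 in LN3 spleen and 2.283 in WT CD8 cells.

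The second comparison set T-ALL cells of the LN3 spleen against WT CD8 cells. The leukaemia cells had higher levels of Notch pathway genes (8 of 11) and of double-positive thymocyte genes (7 of 15, with 2 lower), and both list calls held with an estimated correlation. G2/M (20 of 20), DNA replication (24 of 24) and ribosome biogenesis genes (13 of 18) were higher, and naive T-cell (13 of 15), cytotoxic (13 of 17) and interferon-response genes (14 of 20) lower. These list calls were lost with an estimated correlation, at adjusted p = 0.061, 0.164, 0.379, 0.169, 0.164 and 0.296 in that order. The control, enriched for CD8 T cells, also differed from WT thymocytes in most of these lists. There, 20 of 20 G2/M, 20 of 24 replication and 12 of 15 double-positive genes were lower in WT CD8 cells. Naive (12 of 15), cytotoxic (15 of 17) and interferon-response genes (6 of 20) were higher. For these lists, a trait of the leukaemia cells cannot be told apart from the choice of control. Notch1 was 6.56-fold higher, at 1974 ± 881 against 300.8 ± 63.9 CPM (log2 difference 2.71, SE 0.40, adjusted p = 0.00041), Myc 4.23-fold, at 327 ± 12.8 against 77.33 ± 13.5 CPM (2.08, SE 0.30, adjusted p = 0.000368), and Igf1r 3.48-fold (1.80, adjusted p = 0.00446). Cd8a fell by 2.20 (adjusted p = 0.00192), from 815.4 to 177.3 CPM. Cd4 was low in both groups, at 13.88 and 20.19 CPM (−0.53, adjusted p = 0.585), and Lmo2 (1.08, adjusted p = 0.318) and Nup98 (0.21, adjusted p = 0.407) did not pass.

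Of 11 Notch pathway genes, 8 were higher, 9 adjusted over the list alone (median 2.71, camera adjusted p = 3.94e-08, adjusted p = 0.0487 with an estimated correlation). Notch3 (chromosome 17, 32120820 to 32166852) rose from 1.795 ± 1.15 to 296.8 ± 121 CPM (log2 difference 7.41, SE 0.53, adjusted p = 2.62e-06), and Heyl by 7.23 (adjusted p = 5.06e-06). Of 15 double-positive thymocyte genes, 7 were higher and 2 lower, 9 and 2 adjusted over the list alone (camera adjusted p = 1.59e-05, adjusted p = 0.0455 with an estimated correlation). Rag1 rose from 2.283 to 258.2 ± 159 CPM (6.82, adjusted p = 0.000166) and Arpp21, a thymocyte RNA-binding protein gene, from 1.31 to 144.3 ± 9.97 CPM (6.79, adjusted p = 4.07e-07). In contrast, Cd8b1 fell by 2.57 (adjusted p = 0.000291). All 20 G2/M genes were higher, also adjusted over the list alone (median 3.79, camera adjusted p = 1.13e-23, adjusted p = 0.061 with an estimated correlation). Among them were cyclin B1, Ccnb1 (21.6-fold, adjusted p = 0.000141), and Cdk1 (16.2-fold, adjusted p = 0.000128). All 24 DNA replication genes were higher, also adjusted over the list alone (median 2.75, camera adjusted p = 6.1e-21, adjusted p = 0.164 with an estimated correlation). The leading examples were Uhrf1 (15-fold, adjusted p = 0.000209) and Rrm2 (12.5-fold, adjusted p = 0.000646). Ribosome biogenesis genes were higher in 13 of 18 cases, 15 adjusted over the list alone (camera adjusted p = 2.37e-05, adjusted p = 0.379 with an estimated correlation). Nolc1 and Nop58, nucleolar protein genes, were 3.37-fold and 3.17-fold higher (adjusted p = 0.00278 and 0.00309). Glycolysis had 6 higher genes of 16, also adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.0774). Gapdh was 5.26-fold higher (adjusted p = 0.0014).

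Of 15 mature naive T-cell genes, 13 were lower, 14 adjusted over the list alone (median −3.74, camera adjusted p = 8.91e-10, adjusted p = 0.169 with an estimated correlation). Il7r fell by 5.29 (adjusted p = 9.54e-05), from 546.7 to 14.07 CPM, and Dapl1 was also lower (−5.85, adjusted p = 0.00241). Of 17 cytotoxic genes, 13 were lower, 15 adjusted over the list alone (median −3.56, camera adjusted p = 4.35e-09, adjusted p = 0.164 with an estimated correlation). The leading examples were the killer-receptor genes Klrc1 (−6.27, adjusted p = 0.00191) and Klrk1 (−5.60, adjusted p = 0.000285). Interferon-response genes were lower in 14 of 20 cases, also adjusted over the list alone (median −1.6, camera adjusted p = 1.46e-07, adjusted p = 0.296 with an estimated correlation). Examples were Oas2 (−3.93, adjusted p = 0.000111) and Ifit3 (−3.90, adjusted p = 0.000182). In MHC class I presentation 5 genes were lower and 2 higher of 16, 6 and 2 adjusted over the list alone (camera adjusted p = 0.137), against 8 lower and 0 higher with library totals and 6 and 0 with upper-quartile factors. Its regulator Nlrc5 fell by 2.48 (adjusted p = 0.00129) and the class I heavy chain H2-K1 by 2.19 (adjusted p = 0.00848). Of T-cell receptor signalling genes, 3 were lower and 1 higher of 21, 3 and 0 adjusted over the list alone (camera adjusted p = 0.534). Among them was Nfatc2 (−1.65, adjusted p = 0.00697). That list's median of 0.0168 lay above its mean of −0.172 and turned negative with library totals or upper-quartile factors.

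Of 22 cytokine receptor genes, 15 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 7.2e-05, adjusted p = 0.164 with an estimated correlation). Il18r1 fell by 5.06 (adjusted p = 2.87e-05), and Il9r was 18.3-fold higher (adjusted p = 1.45e-05). Of 18 chemokine receptor genes, 6 were lower and 2 higher, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0283, adjusted p = 0.345 with an estimated correlation, and 0.0645 without WT CD8 1). Cxcr6 fell by 5.22 (adjusted p = 7.28e-07), Cx3cr1 by 3.97 (adjusted p = 0.00112), and Ccr4 was 24.4-fold higher (adjusted p = 1.47e-05). Integrins were lower in 9 of 24 cases, also adjusted over the list alone (camera adjusted p = 0.00669, adjusted p = 0.296 with an estimated correlation). Examples were Itgae (−4.23, adjusted p = 7.29e-05) and Itga2 (−4.23, adjusted p = 0.00192). Of 22 receptor tyrosine kinase genes, 4 were higher and 2 lower, also adjusted over the list alone (median −0.549, mean 0.344, camera adjusted p = 0.652), and Pdgfrb rose from 1.956 to 493.7 ± 194 CPM (log2 difference 7.97, SE 0.47, adjusted p = 7.28e-07). Irs1 was higher by 7.43 (adjusted p = 0.000125). Of 19 T-ALL tumour suppressors, 12 were higher and 1 lower, 14 and 1 adjusted over the list alone (camera adjusted p = 0.000181, adjusted p = 0.0455 with an estimated correlation). With library totals 6 were higher, and with upper-quartile factors 7. The leading examples were Cdkn2a (80.9-fold, adjusted p = 0.000169) and the histone methyltransferase gene Ezh2 (6.38-fold, adjusted p = 7.29e-05). In contrast, Cdkn1b fell by 1.12 (adjusted p = 0.00265). In the BCL2 family 3 genes were higher and 4 lower of 16, 4 and 5 adjusted over the list alone (camera adjusted p = 0.9), and Bcl2 itself was lower (log2 difference −2.27, adjusted p = 0.000119). The list's median of 0.286 lay above its mean of −0.0179 and turned negative with library totals or upper-quartile factors. Immune checkpoints had 1 higher and 3 lower genes of 14, also adjusted over the list alone (camera adjusted p = 0.219). Pdcd1 was 6.83-fold higher (adjusted p = 0.000873) and Vsir fell by 2.64 (adjusted p = 0.00187). Progenitor transcription factors had 1 lower gene of 14, 0 adjusted over the list alone (camera adjusted p = 0.452), and of 3 HoxA genes edgeR, limma and DESeq2 each called 0, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.345).

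Of the largest rises, Vgll1 was at 83.76 ± 68.5 CPM, a ratio of 2710 to WT CD8 cells (counting interval 928 to 13200; adjusted p = 0.00392), and Iltifb was at least 73-fold higher. Lmcd1, a LIM-domain protein gene, was at 144.7 ± 8.69 against 0.08352 CPM (adjusted p = 2.9e-06), and Sall3 at 86.12 against 0.06487 CPM (adjusted p = 1.02e-05). Hist1h2ah, a replication histone gene whose messenger normally lacks a poly(A) tail, was at least 99.4-fold higher (10.76 ± 5.72 CPM against no count). Of the largest falls, the NK receptor gene Ncr1 was at a lower level (−6.56, adjusted p = 0.00903, and 0.0535 without WT CD8 1), as were Klrc2 (−6.09, adjusted p = 0.00231) and Samd3 (−6.21, adjusted p = 0.000205), and Klra6 was lower by a ratio of 129 (43.8 to 626).

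edgeR called 3740 genes higher and 2713 lower between LN3 spleen and WT CD8 cells (57.96% higher), 3199 and 2520 by 2-fold or more, with 9128 at an unadjusted p under 0.05. With library totals or upper-quartile factors, which moved the median of all genes by −0.401 and −0.328, 40.02% and 41.68% of the calls were higher. With either, T-cell receptor signalling had 7 lower and 0 higher genes, checkpoints 5 lower and glycolysis 3 lower, and with library totals receptor tyrosine kinases had 4 lower and progenitor factors 3 lower. Without WT CD8 1, 2416 genes were higher and 1663 lower, and without LN3 spleen 3, 1430 were lower. The ribosomal RNA feature took 6.47 ± 2.8% of counts in LN3 spleen and 0.952 ± 0.447% in WT CD8 cells (exact two-sided permutation p = 0.1; 0.222 adjusted). With its level as a covariate, 3340 of the 6453 calls remained in the same direction, and 5 of the 61 called genes that the rule for named genes took lost their call. The share did not overlap between the groups (4.83% or more in LN3 spleen, 1.45% or less in WT CD8 cells). The covariate was thus partly confounded with the groups, and a lost call cannot be put down to ribosomal RNA.

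Markers of other cells moved with these groups. Erythroid markers were higher in LN3 spleen in 7 of 13 cases (3 with library totals as scaling), 10 adjusted over the list alone (median 3.68, camera adjusted p = 0.00089, adjusted p = 0.379 with an estimated correlation), with haemoglobin at 0.334 ± 0.162% of counts against 0.0289 ± 0.0345% (exact two-sided permutation p = 0.1; 0.222 adjusted) and Hbb-bs and Hba-a1 at 4.05 and 4.27 (adjusted p = 0.0892 and 0.0837). NK-cell markers were lower in 7 of 9 cases, 8 adjusted over the list alone (camera adjusted p = 0.00033, adjusted p = 0.3 with an estimated correlation). Among them was Txk (−3.15, adjusted p = 7.74e-06). Myeloid (camera adjusted p = 0.084), dendritic (0.327), B-cell (0.296), stroma (0.718) and platelet markers (0.96), dissociation stress (0.452), mitochondrially encoded (0.137) and sex-linked genes (0.9) did not pass. The myeloid gene Lyz2 reached 532.3 ± 608 CPM in WT CD8 cells and 129.3 ± 162 in LN3 spleen (−2.04, adjusted p = 0.159), and the B-cell genes Ighm and Ighd were at 0.04 and 0.25 (adjusted p = 0.966 and 0.8). Without LN3 spleen 1 the value of Ighd turned to −1.50 (adjusted p = 0.0366), and without the 3 libraries with the strongest GC rise to −1.44 (adjusted p = 0.0377).

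**Figure D3:**
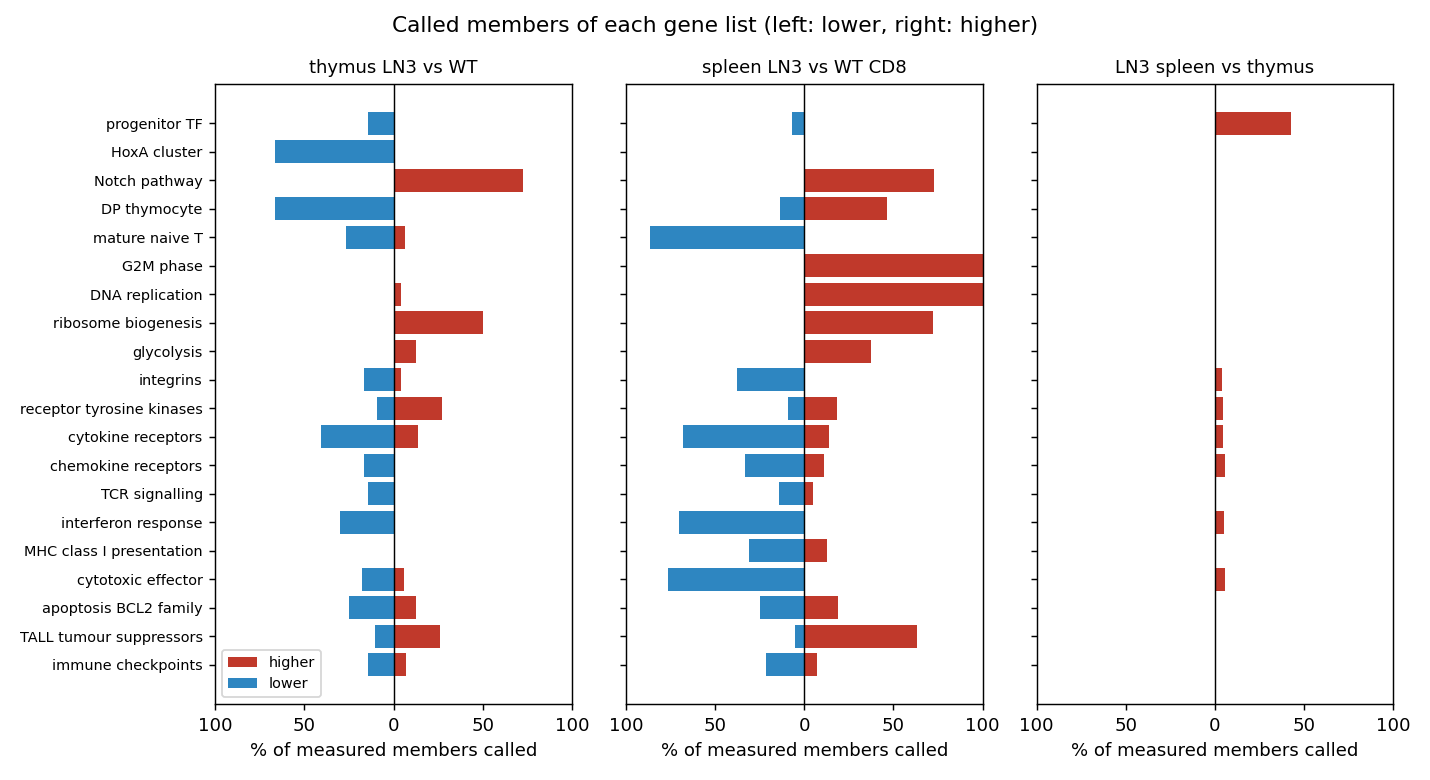
Percent of the measured members of each of 20 programme lists that edgeR called lower (bars to the left) or higher (bars to the right), in thymus LN3 against WT, spleen LN3 against WT CD8 cells and LN3 spleen against LN3 thymus. Notch pathway bars point right in both LN3 against WT comparisons (8 of 11 genes in each), and G2/M bars reach all 20 genes in the spleen comparison.

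Both LN3 against WT comparisons, which share no library, called 880 genes higher, 69.51% of the thymus calls, where independent lists would share 226.6. They called 590 genes lower (54.23%; 141.3 for independent lists) and 58 in opposite directions (359.1). Notch1, Myc, Igf1r, Heyl, Pdgfrb, Irs1, Il9r, Cdkn2a, Vgll1, Iltifb and Sall3 were among the genes higher in both, and Cd8a, Il7r, Itgae, Cxcr6, Ifit3, Klrk1, Bcl2, Vsir, Ntrk3 and Txk among those lower in both. In the thymus, the call of Bcl2 ended without LN3 thymus 1, LN3 thymus 2, WT thymocyte 1 or WT thymocyte 2 (adjusted p up to 0.132). The call of Vsir ended without LN3 thymus 1, LN3 thymus 2, WT thymocyte 1 or WT thymocyte 3 (up to 0.103), and that of Klrk1 without LN3 thymus 1, LN3 thymus 3, WT thymocyte 1 or WT thymocyte 2 (up to 0.139). In the spleen, the call of Ntrk3 (−1.38, adjusted p = 0.00207) ended with limma on the variance-stabilized values (adjusted p = 0.157) and with the length correction (adjusted p = 0.101). Without WT thymocyte 1 the shared counts were 449 higher and 344 lower, and without WT thymocyte 2 579 higher.

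The comparison of LN3 spleen with LN3 thymus asked how T-ALL cells differed between the organs. Fewer genes were called than against WT: 145 genes were higher in the spleen and 6 lower, all by 2-fold or more, with 1817 at an unadjusted p under 0.05. The number of calls also depends on the spread between libraries, so it does not measure the size of the difference. The largest rises were in erythroid genes: carbonic anhydrases Car1 (chromosome 3, 14766216 to 14808368), at 171.9 ± 156 against 0.1117 CPM (log2 difference 10.50, SE 1.14, adjusted p = 0.00624), and Car2 (10.21, adjusted p = 0.00706), and the anion exchanger Slc4a1 (10.33, adjusted p = 0.0333). Notch1 (−0.24, adjusted p = 0.911), Myc (0.10, adjusted p = 0.952), Igf1r (−0.35, adjusted p = 0.871), Cd4 (−1.62, adjusted p = 0.564), Cd8a (−0.74, adjusted p = 0.677), Nup98 (0.14, adjusted p = 0.9) and Lmo2 (3.02, adjusted p = 0.186) did not pass. Lmo2 was at 36.84 ± 7.86 CPM in the spleen and 4.436 ± 5.84 in the thymus. Arg1 and Ksr2 fell by 3.82 and 1.71 (adjusted p = 0.0151 and 0.049).

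Of 13 erythroid markers, 8 were higher in LN3 spleen (2 with library totals as scaling and 5 with upper-quartile factors), 13 adjusted over the list alone (median 6.34, camera adjusted p = 2.9e-33, adjusted p = 0.0591 with an estimated correlation), and haemoglobin genes took 0.334 ± 0.162% of counts against 0.00396 ± 0.00548% (exact two-sided permutation p = 0.1; 0.222 adjusted). Progenitor transcription factors were higher in 6 of 14 cases, 10 adjusted over the list alone (median 2.96, camera adjusted p = 1.07e-24, adjusted p = 0.067 with an estimated correlation), with Tal1, also an erythroid regulator, at 40.9 ± 25.6 against 0.1071 CPM (8.46, adjusted p = 0.00624) and Bcl11a, also a B-cell regulator, higher by 4.65 (adjusted p = 0.0151). Of 15 B-cell markers, 1 was higher, 14 adjusted over the list alone (median 3.27, camera adjusted p = 8.57e-19, adjusted p = 0.167 with an estimated correlation), with Ighd at 3.71 (adjusted p = 0.0514). Of 7 platelet markers, 2 were higher, 5 adjusted over the list alone (camera adjusted p = 3.94e-09, adjusted p = 0.0765 with an estimated correlation). Among them was the integrin Itga2b (3.37, adjusted p = 0.0342). Chemokine receptors had 1 higher gene of 18, the eosinophil receptor Ccr3 (adjusted p = 0.049), 5 adjusted over the list alone (camera adjusted p = 1.2e-07, adjusted p = 0.0765 with an estimated correlation), and cytotoxic genes 1 of 17, Eomes (2.24, adjusted p = 0.0461), 5 adjusted over the list alone (camera adjusted p = 4.95e-06, adjusted p = 0.45 with an estimated correlation). Kit, also a receptor tyrosine kinase (1 of 22 genes; camera adjusted p = 0.451), rose by 2.52 (adjusted p = 0.0342), Tgfbr3 (1 of 22 cytokine receptors; camera adjusted p = 0.54) by 1.19 (adjusted p = 0.0452) and the antiviral gene Rsad2 (1 of 20 interferon genes; camera adjusted p = 0.788) by 3.50 (adjusted p = 0.0363).

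The Notch list did not pass between the organs (camera adjusted p = 0.0546). Of its 11 genes, edgeR, DESeq2 and limma each called 0, with 2 at an unadjusted p under 0.05. Camera placed G2/M (median 0.588, adjusted p = 0.000127), DNA replication (0.419, adjusted p = 0.00029), ribosome biogenesis (adjusted p = 0.0108), MHC class I (adjusted p = 0.00228), myeloid (adjusted p = 3.59e-07), dendritic (adjusted p = 2.54e-06) and checkpoint genes (adjusted p = 0.0172) higher, naive T-cell genes higher (adjusted p = 0.0412) and double-positive genes lower (adjusted p = 0.036) in the spleen. With an estimated correlation each of these was lost, at adjusted p = 0.469 for G2/M, MHC class I, myeloid, dendritic and checkpoint genes, 0.563 for replication, 0.565 for ribosome biogenesis, 0.63 for naive T-cell and 0.342 for double-positive genes. The naive call ended without LN3 thymus 1 or LN3 spleen 1 (up to 0.986), the double-positive call without LN3 thymus 1, LN3 thymus 2, LN3 spleen 1 or LN3 spleen 2 (up to 0.148), and the replication and ribosome calls without LN3 thymus 3 or LN3 spleen 3 (up to 0.166 and 0.612). The MHC call ended without LN3 thymus 1 (0.103), and the checkpoint call without LN3 thymus 1, LN3 spleen 1 or LN3 spleen 2 (up to 0.245).

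With library totals as scaling, the calls in the B-cell, platelet, chemokine receptor, cytotoxic, receptor tyrosine kinase, cytokine receptor and interferon lists ended. Counts in this comparison moved with single libraries. Higher genes numbered 0 without LN3 thymus 1, 6 without LN3 thymus 2, 45 without LN3 thymus 3, 51 without LN3 spleen 1, 207 without LN3 spleen 2, 49 without LN3 spleen 3 and 1 without the 3 libraries with the strongest GC rise, against 586 by DESeq2. The 15 called genes that the rule for named genes took from this comparison all lost their call without LN3 thymus 1 (adjusted p of 0.0714 for Car1, Car2 and Tal1), 13 did without LN3 thymus 2, 11 without LN3 thymus 3, 8 without LN3 spleen 1, 3 without LN3 spleen 2 and 10 without LN3 spleen 3. Lower genes numbered 0, 1 and 10 without LN3 thymus 1, 2 and 3, 2, 10 and 3 without LN3 spleen 1, 2 and 3, and 61 by DESeq2.

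The WT groups were compared to show how the controls of the organs differ. WT CD8 cells had lower levels of 12 of 15 double-positive thymocyte genes than WT thymocytes, a list call that held with an estimated correlation. G2/M (20 of 20) and replication genes (20 of 24) were lower too, and naive (12 of 15) and cytotoxic genes (15 of 17) higher. These list calls were lost with an estimated correlation, at adjusted p = 0.0825, 0.306, 0.19 and 0.122 in that order. Rag1 fell from 4871 to 2.283 CPM (log2 difference −11.06, adjusted p = 4.45e-05), and Arpp21 from 436.8 to 1.31 CPM (adjusted p = 6.92e-08). Cd4 (−5.80, adjusted p = 0.000921) and Notch3 (−6.09, adjusted p = 1.88e-05) were lower too. Of 15 double-positive genes, 12 were lower, 14 adjusted over the list alone (camera adjusted p = 3.75e-29, adjusted p = 0.000269 with an estimated correlation). All 20 G2/M genes (camera adjusted p = 1.86e-23, adjusted p = 0.0825 with an estimated correlation) and 20 of 24 replication genes (22 adjusted over the list alone; camera adjusted p = 1.24e-15, adjusted p = 0.306 with an estimated correlation) were lower. Naive T-cell genes were higher in 12 of 15 cases (13 adjusted over the list alone; camera adjusted p = 2.18e-12, adjusted p = 0.19 with an estimated correlation) and cytotoxic genes in 15 of 17 (17 adjusted over the list alone; camera adjusted p = 6.88e-16, adjusted p = 0.122 with an estimated correlation), such as Klrd1 (5.73, adjusted p = 0.00238). Bcl2 rose 3.3-fold (adjusted p = 0.00115) and Bcl2l1 fell by 3.54 (adjusted p = 0.000129). Myeloid markers were higher in 15 of 20 cases (19 adjusted over the list alone; camera adjusted p = 1.46e-08, adjusted p = 0.328 with an estimated correlation) and B-cell markers in 8 of 15 (13 adjusted over the list alone; camera adjusted p = 3.21e-07, adjusted p = 0.328 with an estimated correlation), with Ighd higher by 4.02 (adjusted p = 0.00477). NK-cell markers were higher in 6 of 9 cases (8 adjusted over the list alone; camera adjusted p = 0.000378, adjusted p = 0.328 with an estimated correlation), and the NK receptor Ncr1 by 7.85 (adjusted p = 0.00948, and up to 0.0536 without WT thymocyte 1 or 3). edgeR called 1513 genes higher and 1774 lower. Higher genes numbered 717 without WT thymocyte 1, 915 without WT thymocyte 2, 858 without WT CD8 1 and 843 without WT CD8 2, and lower genes 1013 without WT CD8 1 and 1179 without WT CD8 2. Notch1 (−0.59, adjusted p = 0.332), Myc (0.23, adjusted p = 0.673), Igf1r (−0.33, adjusted p = 0.635), Nup98 (0.12, adjusted p = 0.735) and Cd8a (−1.18, adjusted p = 0.0646) did not pass. Lmo2 was 9.2-fold higher (adjusted p = 0.0307), a call that ended without WT CD8 1, WT CD8 2 or any WT thymocyte library (up to 0.115).

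The last test asked whether the LN3 against WT difference itself differed between the organs, as the spleen difference minus the thymus difference. Values are signed, so a smaller value can be a deeper fall in the spleen. The controls of the organs are also different cells. edgeR called 688 genes with a larger value in the spleen and 187 with a smaller one, with 3648 at an unadjusted p under 0.05. Rag1 (10.07, SE 1.13, adjusted p = 0.000741), Arpp21 (8.06, adjusted p = 7.34e-07) and Notch3 (5.37, adjusted p = 0.000741) were among the larger ones. Cxcr6 (−2.46, adjusted p = 0.00435) and the granzyme gene Gzmm (−3.59, adjusted p = 0.00708) were among the smaller ones. Notch1 (0.35, adjusted p = 0.757), Myc (−0.13, adjusted p = 0.893), Igf1r (−0.02, adjusted p = 0.991), Cd8a (0.44, adjusted p = 0.715), Lmo2 (−0.18, adjusted p = 0.951) and Nup98 (0.01, adjusted p = 0.987) did not pass. The Notch list had 2 larger and 1 smaller of 11 genes (camera adjusted p = 0.256). Larger values numbered 431 without LN3 thymus 3, 380 without WT CD8 1 and 412 without WT CD8 3. Smaller values numbered 76 without WT thymocyte 1, 93 without LN3 thymus 3, 120 without LN3 spleen 2, 105 without LN3 spleen 3 and 83 without WT CD8 1.

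One T-cell receptor beta V segment, Trbv5 (chromosome 6, 41062332 to 41062803), held most beta V counts in every LN3 library. Its share was 65.6% (95% interval 64.4 to 66.8), 78.7% (77.5 to 79.9) and 88.5% (87.8 to 89.2) in LN3 thymus 1 to 3 and 81.1% (79.5 to 82.6), 90.3% (89.6 to 91) and 95.9% (95.3 to 96.5) in LN3 spleen 1 to 3. The means were 77.6 ± 11.5% in LN3 thymus against 3.83 ± 0.316% in WT thymocytes, and 89.1 ± 7.49% in LN3 spleen against 2.28 ± 0.302% in WT CD8 cells (exact two-sided permutation p = 0.1 for each, the smallest 3 against 3 libraries allow; 0.222 adjusted over 20 tests). Between the LN3 organs that test gave p = 0.2 by exact permutation (0.333 adjusted).

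**Figure D4:**
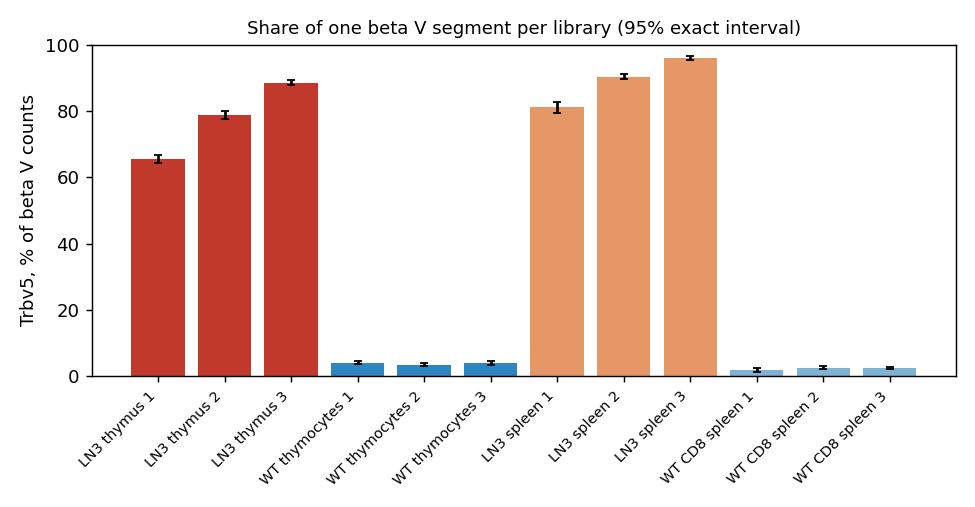
Share of T-cell receptor beta V counts assigned to Trbv5 (y axis, percent) in each of the 12 libraries (x axis), with exact 95% intervals. The 6 LN3 libraries lie between 65.6% and 95.9%, and no WT library is above 4.06%.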

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

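The tests of nucleated erythroid cells, of the shared receptor segment and of a shared leukaemia were chosen after their results were seen. The corrections for GC content and transcript length were added after the data were seen, with their bounds set before their results. The erythroid test by WT thymocytes, the B-cell test and the counts of other splits were set before their results.

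By edgeR's interaction test, the spleen LN3 difference minus the thymus difference was positive for 688 genes and negative for 187. A negative value can be a deeper fall in the spleen, as for naive T-cell genes (median −1.45 in the thymus and −3.74 in the spleen). A positive value can come from the controls, as for double-positive genes, whose median was −4.29 between the WT groups and −0.454 between the LN3 organs. Of 60 relabellings of genotype within the organs, drawn from 200 with the real one included, 4 gave as many called genes (real 875, highest other 7430). The 3 larger relabellings exchanged the labels of all spleen libraries, which by arithmetic turns a genotype difference shared by the organs into an interaction, a structure of the samples. The relabellings therefore decide nothing about chance for the interaction. For genes called in the same direction in both organs, 1 of 60 relabellings, the real one, reached 1470, with 58 as the highest other. That share is under 0.05 for libraries taken as separate, but it does not exclude chance. Relabellings that mix LN3 and WT libraries within a group also move the genotype difference into the spread, which by itself lowers their counts. LN3 thymus 3 and LN3 spleen 2 may hold cells of one leukaemia (alpha V shares correlated at Pearson r = 0.969 and Spearman 0.73), so the organs may not be independent.

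The largest interaction values among named genes were 10.07 for Rag1, 9.54 for Hist1h2ah (its call ended with the replicate number as a block), 8.7 for Acan, 8.057 for Arpp21 and 7.875 for Camkv. The call of Camkv ended without WT thymocyte 3, WT CD8 1 or WT CD8 3 (adjusted p up to 0.0638). Cd4 was at 4.179 (adjusted p = 0.0444), a call that ended without any 1 library other than LN3 thymus 1 and WT CD8 1 (up to 0.108). The smallest values were −5.835 for Pde2a, −5.676 for Sele, −5.183 for Ace, −4.98 for Art2b and −4.945 for Lcn4. The call of Ace ended without WT thymocyte 1 (0.0547), and that of Pde2a in 10 of the 12 fits without 1 library (up to 0.118).

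As lists, the organs' differences were further apart, with a larger value in the spleen, for double-positive thymocyte genes (camera adjusted p = 8.72e-31, adjusted p = 9.48e-05 with an estimated correlation) and G2/M genes (1.05e-32, adjusted p = 0.0554 with an estimated correlation). The same held for DNA replication (2.81e-22, adjusted p = 0.233 with an estimated correlation) and erythroid markers (3.45e-06, adjusted p = 0.329 with an estimated correlation). It also held for HoxA genes (0.02, adjusted p = 0.431 with an estimated correlation) and T-ALL tumour suppressors (0.0335, adjusted p = 0.233 with an estimated correlation). The HoxA call ended without LN3 thymus 1, LN3 spleen 2 or WT CD8 2 (up to 0.231), and the tumour suppressor call without WT thymocyte 1, LN3 spleen 2 or WT CD8 2 (up to 0.0624). Values were smaller in the spleen for naive T-cell genes (1.36e-08, adjusted p = 0.314 with an estimated correlation), cytotoxic genes (1.43e-08, adjusted p = 0.308 with an estimated correlation) and NK-cell markers (0.00329, adjusted p = 0.537 with an estimated correlation). They were smaller too for interferon-response genes (0.00284, adjusted p = 0.712 with an estimated correlation, and 0.0693 without LN3 thymus 2). Myeloid markers (0.00329, adjusted p = 0.806 with an estimated correlation) lost the call without WT thymocyte 2 or WT CD8 2 (up to 0.084). Mitochondrially encoded genes (0.00708, adjusted p = 0.712 with an estimated correlation) lost it without LN3 thymus 2, WT thymocyte 2 or WT CD8 3 (up to 0.106).

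Genes higher in LN3 spleen than in LN3 thymus included 8 of 13 erythroid markers (2 with library totals as scaling). The called genes outside the B-cell list had a median log2 ratio of 0.255 between LN3 spleen 1, rich in immunoglobulin, and the mean of LN3 spleen 2 and 3. This cannot decide about RNA of B and plasma cells, because the call itself favours genes with little spread between these same libraries. The median of B-cell markers in that ratio was 2.59, but it was also 3.16 for NK-cell, 1.91 for dendritic and 1.25 for myeloid markers. A planned test of erythroid RNA, by the ratio of WT thymocyte 1 over WT thymocyte 2 (median 0.174), was void, because erythroid markers other than globins moved by −0.198 there. A replacement chosen afterwards, WT CD8 2 over the mean of WT CD8 1 and 3, gave a median of 1.28 over called genes outside the erythroid list, but it does not single out erythroid cells, since medians were also 1.97 for myeloid, 1.13 for B-cell and 1.54 for G2/M genes there, beside 2.95 for erythroid markers. RNA of B and plasma cells and RNA of nucleated erythroid cells therefore stay open, and a change within the leukaemia cells between organs was not tested.

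Trbv5 held most beta V counts in all 6 LN3 libraries. Sequence shared with transcripts of WT cells was argued against as the source by a share of at most 4.06% in WT libraries. This does not cover a transcript present in LN3 cells alone. A single leukaemia passed between the mice was argued against by Xist above 100 CPM in 3 of the 6 LN3 libraries. The chance that 2 independent clones draw the same segment at WT thymocyte shares was 0.0636, but that for 3 clones was 0.00502. Chance may therefore account for 2 clones and poorly for more, and the leading alpha V segments differed between most LN3 libraries. A rearranged receptor gene carried by the strain stays open and was not tested.

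WT thymocyte 3 stood apart from WT thymocytes 1 and 2, with a standard deviation of its log2 deviations of 0.835. Transcript length was argued against as the source, since correcting for it lowered that value by 2.23%, to 0.817. The correction for GC content lowered it by 26.1%, to 0.617, which lies between the bounds set beforehand, so GC bias cannot be told apart from other sources. No biological explanation was tested.

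Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. In every comparison 1 split, the real one, reached its count: 1479 genes against 0 in the highest other for the thymus, 8312 against 0 for the spleen, 111 against 19 for LN3 spleen against LN3 thymus and 2726 against 1 for the WT groups.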

How the results depend on the processing

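The corrections for GC content, transcript length and ribosomal RNA counts and the fit without the 3 libraries with the strongest GC rise were chosen after the data were seen. Under all alternatives, 6749 of 7335 values of named genes kept their side of the threshold and, where called, their direction. So did 1463 of 1680 list tests, and 199 of 274 counts stayed within 1.5 times. Results not called under either setting were taken as kept even where their sign changed, so these totals do not measure the direction of uncalled results. The causes of the changes below were not tested, except that a fold threshold leaves fewer calls by construction. Counts of few reads limit genes near the floor, and the fit of 2 groups gives no interaction value.

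In the thymus, higher genes numbered 811 with 2 groups fitted and 726 with a fold threshold, and lower genes 1649 with library totals, 1665 with DESeq2, 668 with 2 groups, 619 with a fold threshold and 1709 with GC correction. In the spleen the fold threshold left 2468 higher and 1740 lower, and the ribosomal RNA covariate 2127 and 1751. For LN3 spleen against LN3 thymus, higher genes numbered 41 with library totals, 586 with DESeq2, 41 with the ribosomal RNA covariate and 1 without the GC-shifted libraries. Lower genes numbered 2 with library totals, 61 with DESeq2, 14 with no filter, 3 with a fold threshold, 3 with the covariate and 0 without the GC-shifted libraries by edgeR. Between the WT groups the fold threshold left 947 higher and 1132 lower. For the interaction, DESeq2 gave 1246 larger and 482 smaller, the fold threshold 457 and 110, GC correction 404 smaller and the covariate 284 smaller. Genes higher in both organs numbered 586 with 2 groups and 510 with a fold threshold, and genes lower in both 1034 with library totals, 946 with upper-quartile factors, 353 with 2 groups, 321 with a fold threshold and 1003 with GC correction.

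With the replicate number as a block, 29 genes were higher and 2 lower in LN3 spleen than in LN3 thymus, and the interaction had 427 larger and 105 smaller values. Of same-numbered pairs, 4 of 18 correlated above 0.1 across genes (from −0.589 to 0.43), and 3 of 12 libraries correlated best with their own number. LN3 and WT samples cannot share an animal, and same-numbered organ pairs within a genotype ran from −0.589 to 0.0214. Xist was at 2.9 CPM in LN3 thymus 2 and 3880 in LN3 spleen 2, and at 0.883 in WT thymocyte 3 and 1740 in WT CD8 3. These pairs therefore came from different animals, while a shared animal stays possible for the other numbers.

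Without 1 library at a time, counts ran from 562 to 1652 higher and 641 to 1085 lower in the thymus, and from 2416 to 3583 higher and 1430 to 2170 lower in the spleen. They ran from 0 to 207 higher and 0 to 10 lower for LN3 spleen against LN3 thymus, from 717 to 1410 and 1013 to 1807 between the WT groups, and from 380 to 664 and 76 to 226 for the interaction. Genes higher in both organs ran from 449 to 1205 and lower in both from 344 to 679. Ighd in the spleen comparison (0.25) reversed to −1.496 without LN3 spleen 1 and −1.442 without the GC-shifted libraries, and ran from −1.496 to 0.7707 without 1 library. The naive T-cell list between LN3 organs reversed without LN3 thymus 1 (adjusted p = 0.739), and its adjusted p ran from 5.28e-05 to 0.986 without 1 library.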

Other observations

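The test of a shared leukaemia was chosen after its pattern was seen.

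Between the WT groups, 5 of 16 MHC class I genes were higher in WT CD8 cells than in WT thymocytes (11 with library totals as scaling), also adjusted over the list alone (camera adjusted p = 0.00027, adjusted p = 0.328 with an estimated correlation). B2m, the class I light chain, was higher by 2.21 on the log2 scale (adjusted p = 0.000518), and H2-K1 by 2.42 (adjusted p = 0.00894, and 0.0506 without WT thymocyte 1). Interferon-response genes were higher in 6 of 20 cases, 7 adjusted over the list alone (camera adjusted p = 0.000368, adjusted p = 0.363 with an estimated correlation), as for the antiviral gene Mx1 (2.40, adjusted p = 0.00582). Of 18 chemokine receptor genes, 9 were higher and 4 lower, 10 and 4 adjusted over the list alone (camera adjusted p = 0.00468, adjusted p = 0.328 with an estimated correlation). Progenitor transcription factors were higher in 9 of 14 cases, 10 adjusted over the list alone (camera adjusted p = 7.95e-05, adjusted p = 0.328 with an estimated correlation), among them Tal1, also an erythroid regulator (5.60, adjusted p = 0.00126). Markers of other cells were higher in this contrast too, as for platelet markers in 3 of 7 cases, 7 adjusted over the list alone (camera adjusted p = 0.0033, adjusted p = 0.328 with an estimated correlation). Erythroid markers were higher in 5 of 13 cases, 7 adjusted over the list alone (camera adjusted p = 0.0486, adjusted p = 0.575 with an estimated correlation, and up to 0.422 without WT thymocyte 2, WT thymocyte 3 or WT CD8 2). In WT CD8 libraries 1 to 3, the mean CPM was 14.19, 21.22 and 4.607 over progenitor factors, 12.37, 62.72 and 4.72 over erythroid markers and 99.82, 210 and 19.36 over myeloid markers. T-ALL tumour suppressors were lower in 5 of 19 cases, 6 adjusted over the list alone (camera adjusted p = 0.00307, adjusted p = 0.0825 with an estimated correlation), as for Ezh2 (−2.32, adjusted p = 0.000302).

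The leading alpha V segments differed between most LN3 libraries. Trav10d held 29.7% of alpha V counts in LN3 thymus 2 (95% interval 27.5 to 32) and Trav5-4 19.2% in LN3 spleen 3 (16.5 to 22.2). The near-identical pair Trav7d-5 and Trav7n-5 led both LN3 thymus 3 (33.7%, 32.2 to 35.2) and LN3 spleen 2 (34.1%, 32.5 to 35.7), as shares of alpha V counts. Beside Trbv5, these same libraries had Trbv13-2 at 7.98% (7.4 to 8.6) and 6.55% (6 to 7.13) of beta V counts.

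A hypothesis from this is that LN3 thymus 3 and LN3 spleen 2 may hold cells of one leukaemia, although their replicate numbers differ. Across 125 alpha V segments without Trav7d-5, Trav7n-5 and Trav17, the shares of these libraries correlated at Pearson r = 0.969. The other 8 pairs of an LN3 thymus and an LN3 spleen library lay at 0.065 to 0.417. By Spearman correlation the pair was at 0.73 and the others at 0.218 to 0.705, so ranks set it little apart. LN3 thymus 2 and LN3 spleen 1, at 0.705, also had the higher correlation of deviations from the group mean across genes (0.526 against 0.465). Both are among the libraries whose counts rose most with GC content (Spearman 0.365 and 0.467). LN3 thymus 2 correlated at 0.538 with WT thymocyte 3, a control library with such a rise too. The correlation of deviations therefore cannot decide about shared cells. Segments are not independent replicates, and the labels do not say which samples share an animal.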
